A study of Mus musculus with 2 samples.

How the data were processed

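Single-cell RNA counts were analysed for CD45-positive cells sorted from 4T1 mammary tumours, with 1 library from tumours of cells expressing shPml and 1 from tumours of cells expressing shCTRL. The 4T1 cells were injected in 50 µl of PBS into the mammary fat pad of BALB/c mice aged 6 to 8 weeks, per the labels' protocols. Tumours were taken 14 days after implantation, digested with 0.25 mg/ml collagenase and 50 U DNase, and treated for 10 min with red cell lysis buffer, per the labels' protocols. How many mice gave each library, and their sex, is not given in the sources used here.

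The authors deposited 1 matrix of counts per library, with whole-number UMI counts for 32285 genes and no normalization. The matrices were made with Cell Ranger 4.0.0, per the file headers. The submitters' processing notes also list the mm10 genome build, R 4.3.3 and Seurat 4.4.0, and the role of R and Seurat is not given in the sources used here. The smallest barcode total in both deposited matrices was 500 UMIs, so barcodes below it had been left out before deposit; by whom is not given in the sources used here. The gene annotation and the sequencing depth in reads are not given there either. Pml and the sex-linked genes were located on the mm10 build.

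Barcodes with at least 200 genes and at most 10% mitochondrial UMIs were kept, 1754 in the shPml library and 856 in the shCTRL library. Doublets were called in each library with Scrublet as run by scanpy (20 principal components) and left out, 3 barcodes in the shPml library and 4 in the shCTRL library. Scrublet does not find doublets of 2 cells of the same type. Counts were scaled to 10000 per cell and log-transformed, and both libraries were clustered together on 2000 variable genes and 30 principal components, with 15 neighbours and Leiden resolution 1.0, without batch correction. T and NK clusters were clustered again in the same way.

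Clusters were named from 25 marker lists fixed before the data were examined. A marker counted as detected with UMIs in at least 10% of a cluster's cells and a mean of at least 25% of that in its highest cluster. A name needed at least 3 detected markers. A cluster stayed unnamed where its 10 leading genes held more markers of another list than of its own, or where its median UMIs were under 1/3 of the typical median of its cells' libraries and none of its own markers led. T cell clusters of the first clustering were exempt, since they were clustered again: clusters 6, 7 and 8 kept the name T cell with 1 marker of another list and 0 of their own among their leading genes. Within T and NK-like cells only the T cell, NK cell and innate lymphoid lists were counted for this, so Ccl5 and Ly6c2, which mark dendritic cells and monocytes, left no subcluster unnamed. Names end in "-like" because no protein was measured. T subclusters led by markers of other lists were compared by number.

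Shares were compared as cells of a class over all cells, or over T and NK-like cells, with exact (Clopper-Pearson) binomial intervals. The ratio of 2 shares, and the ratio of 2 levels, was given an exact conditional Poisson interval. Levels are summed UMIs of a class per 1000000 UMIs of that class in the library (CPM). A gene with 0 counts in a library was given a ratio against a floor of 3 counts over the class. That ratio is not a lower limit, so the lower limit of the exact interval is given beside it. No p-values, standard errors or counts of changed genes were computed, because each group had 1 library. No paired analysis was possible because each group had 1 library.

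The rule for named genes was fixed before the data were examined. It took classes with at least 100 cells in both libraries, and T cells with at least 50 in both. Genes needed at least 50 summed UMIs and a level of at least 20% of that in the class where the gene is highest. Ribosomal, mitochondrial, Gm-named, Rik-named, immunoglobulin, T cell receptor, haemoglobin, Xist and Y-linked genes were left out. The 12 genes per direction with the interval bound farthest from 0 were named, and from each gene list described, the 2 to 4 members with the largest such bound. Pml was named in all classes.

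Of 25 gene lists fixed before the data were examined, members with at least 20 summed UMIs were used where at least 5 remained. The median log2 ratio was compared with 10000 random lists drawn from the same of 20 expression bins, and its counting interval came from 2000 Poisson draws. Shares of cells with a gene were computed after thinning each cell to 500 UMIs, and a cycling cell had at least 2 UMIs of proliferation markers. Of the alternatives tried, 18 were chosen before the data were examined and 14 after seeing the data.

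Depth sets the precision: 1751 shPml cells held 3714867 UMIs and 852 shCTRL cells held 3664836. The methods were tested on simulated data with 200 changed genes. Summed counts were drawn from the Poisson distribution that the intervals assume, so UMIs concentrated in single cells were not part of this check. At the size of the CD8 T-like class the 95% intervals covered 96.3% of the 4403 simulated ratios, and 3.67% of unchanged genes lay outside 0. There, 63.6% of 88 genes with a log2 change of 1 and 93.0% of 86 genes with a log2 change of 2 lay outside 0 with the right sign. At the size of the neutrophil class these were 96.0% of 2319 ratios, 4.35%, 81.3% of 91 genes and 100% of 90 genes. The share interval covered the simulated share in 96.7% of 2000 draws, and 99.9% of 1200 simulated cells of 4 types were named right. The 4 types included no T cell subclasses. Of 40 unchanged simulated lists at each size, 100% and 95% lay in the middle 95% of random lists.

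Computation used Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, with random seed 1.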

Results

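Leukocytes were profiled from tumours of 4T1 cells, a mouse mammary carcinoma line used as a model of triple-negative breast cancer, grown in the mammary fat pad of BALB/c mice. The injected cells carried a short hairpin RNA against Pml (shPml) or a control hairpin (shCTRL). The series asks whether PML, the scaffold protein of PML nuclear bodies, acts as an immune suppressor in this tumour type. Tumours of similar size were taken 14 days after implantation, CD45-positive cells were sorted, and 1 droplet (10x Chromium) library was made per group. CD45 is the surface marker shared by leukocytes. The shPml library held 2268 barcodes and 4227187 UMIs (unique molecular identifiers, 1 per counted transcript), with a median of 1109 UMIs and 595.5 genes per barcode. The shCTRL library held 2244 barcodes and 5044925 UMIs, with a median of 1008 UMIs and 507.5 genes. No barcode in either library had fewer than 500 UMIs. After filtering, 1751 shPml cells with a median of 1300 UMIs and 852 shCTRL cells with a median of 4040 UMIs were analysed. With 1 library per group no difference has a replicate check, and no p-value can be given. Intervals are exact 95% intervals that cover counting error only.

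Pml is on chromosome 9 at 58218076 to 58249786 on the minus strand (mm10). Its transcripts were compared first in every class of leukocyte. In B or plasma-like cells Pml stood at 102 counts per 1000000 UMIs of the class (CPM) in the shPml library and 94.3 in the shCTRL library (log2 ratio 0.11, -0.60 to 0.82). In naive T-like cells the levels were 47.0 and 41.1 CPM (log2 0.19, -1.16 to 1.30), and in regulatory T-like cells 33.0 and 36.6 CPM (log2 -0.15, -1.38 to 0.97). Monocyte or macrophage-like cells had 7 and 3 Pml UMIs (log2 -0.15, -2.28 to 2.44), CD8 T-like cells had 24 and 2 (log2 0.46, -1.55 to 3.59), and neutrophil-like cells had 3 and 0. NK-like cells had 0 and 2 Pml UMIs. In the epithelial-like cells there were 0 Pml UMIs in both libraries, which allows up to 151 CPM in the 22 shPml cells and up to 804 CPM in the 6 shCTRL cells (3 counts of the total). That cluster was named from 3 detected markers. Wfdc2 stood at 1480 CPM there but Epcam and Cdh1 at 0, so these cells cannot be taken as the injected 4T1 cells. The hairpin was expressed in the injected tumour cells, which the CD45 sort should remove, so Pml in the sorted leukocytes does not check the labels.

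Both libraries held neutrophil-like, monocyte or macrophage-like, B or plasma-like and T and NK-like cells, with few epithelial-like cells. Neutrophil-like cells, marked by the calprotectin genes S100a8 and S100a9, made up 12.2% of shPml cells (214 of 1751, 10.7 to 13.8%) and 3.99% of shCTRL cells (34 of 852, 2.78 to 5.53%), a ratio of 3.06 (2.13 to 4.54). B or plasma-like cells, marked by the B cell receptor genes Cd79a and Cd79b, were lower in the shPml library, with 3.66% (64 cells) against 8.45% (72 cells), a ratio of 0.433 (0.304 to 0.614). Monocyte or macrophage-like cells made up 3.08% (54 cells) and 1.995% (17 cells), a ratio whose interval held 1 (1.55, 0.882 to 2.84). Epithelial-like cells numbered 22 and 6. The remaining 1397 shPml and 723 shCTRL cells were T and NK-like. Several T cell clusters were led by genes that also mark other cell types, such as Ccl5, so this class serves here as a denominator. These shares depended on which T cells were counted beside them: outside the clusters with more cells carrying Y-linked than Xist UMIs, described further on, the neutrophil-like share was 47.7% against 5.20%, a ratio of 9.17 (6.36 to 13.6). The B or plasma-like ratio there was 1.29 (0.910 to 1.84), against 0.433 among all cells, and the monocyte or macrophage-like ratio was 4.63 (2.64 to 8.51). The sort, the limit of 10% mitochondrial UMIs and the gap in median depth can each set such shares. The limit left out 22.7% of shPml barcodes (514) and 61.9% of shCTRL barcodes (1388).

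**Figure D1:**
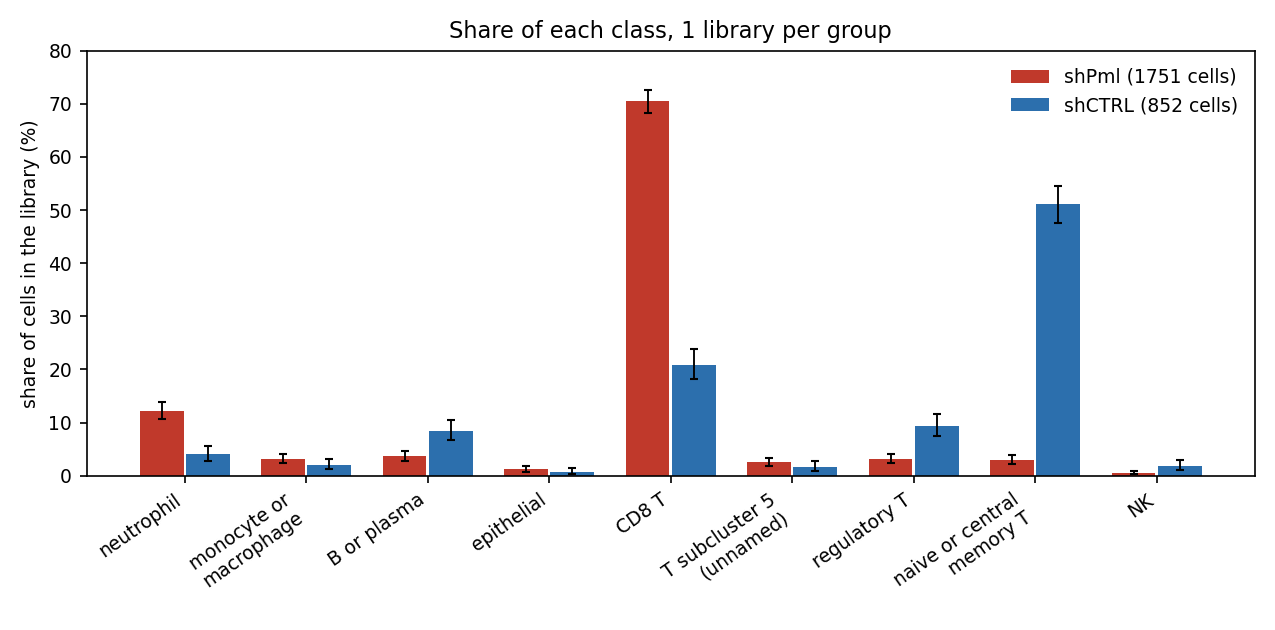
Share of all analysed cells (y axis, percent) in each class (x axis) in the shPml library (red, 1751 cells) and the shCTRL library (blue, 852 cells). Error bars are exact 95% binomial intervals; CD8 T-like cells took 70.5% and 20.9%, and naive or central memory T-like cells 3.03% and 51.1%.

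The T and NK-like cells of the shPml library were mostly CD8 T-like, and those of the shCTRL library mostly naive or central memory T-like. The naive subcluster, marked by the transcription factor gene Lef1, held 3.79% of T and NK-like cells in the shPml library (53 of 1397) and 60.2% in the shCTRL library (435 of 723), a ratio of 0.0631 (0.0465 to 0.0840). Regulatory T-like cells, marked by the lineage factor gene Foxp3, held 3.94% (55 cells) and 11.1% (80 cells), a ratio of 0.356 (0.248 to 0.508). NK-like cells numbered 9 and 16. Subclusters 0 to 4 were named from the CD8 T cell marker list, which includes Cd8a, Cd8b1, Gzmb and Nkg7. Subclusters 0, 1 and 3 had 3 detected markers of that list, and subclusters 2 and 4 had 4. Together these subclusters held 88.4% (1235 cells) and 24.6% (178 cells), a ratio of 3.59 (3.07 to 4.23). Gates on UMIs of Cd8a or Cd8b1, Cd4 and Foxp3 in each cell, without clusters, gave 58.8% (821 cells) and 35.3% (255 cells), a ratio of 1.67 (1.45 to 1.93). Of the 6 genes in that marker list, 0 were among the 10 leading genes of subclusters 0, 1, 3 and 4, and 1 (Gzmb) was in subcluster 2. Cd8a stood at 474 CPM in these subclusters against 61.5 in regulatory T-like and 160 in naive T-like cells. Their shCTRL cells had a median of 828.5 UMIs, against 4040 over all shCTRL cells. Their sizes are given by number, because subcluster 3 was led by Ccl5 and Ly6c2, which also mark other cell types. Subcluster 0, led by histone genes such as Hist1h1b, held 24.8% and 5.95% of T and NK-like cells. Subcluster 1, led by Nrgn and Xcl1, held 17.1% and 4.84%. Subcluster 2, led by Cxcr6 and Gzmb, held 19.0% and 8.30%. Subcluster 3 held 15.8% (221 cells) and 1.38% (10 cells), and subcluster 4, led by mitotic genes such as Ube2c, 11.6% and 4.15%. Subcluster 5 stayed unnamed because the NK cell markers Gzma and Klre1 were among its leading genes, and held 45 and 14 cells. It had 5 detected CD8 T cell markers and Cd8a at 717 CPM, so the missing name does not mean that CD8 T cells were absent from it. A cluster found mostly in 1 of 2 libraries may stand for that library and not for a cell type. At a Leiden resolution of 2.0 within T and NK-like cells the regulatory T-like ratio turned to 1.59, because the subcluster with the Foxp3 marker stayed unnamed there, and with every barcode kept it was 0.908. It turned to 3.12 outside the clusters with Y-linked UMIs described further on, where no CD8 T-like cells remain in the denominator.

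Many barcodes were present in both libraries, and these were not spread evenly over the cell types. Of 266 shared barcodes, most belonged to CD8 T-like cells: 174 of the 178 shCTRL CD8 T-like barcodes (97.8%, 94.3 to 99.4%) were also barcodes of the shPml library, where 172 of them were in the same class. The shPml library held more UMIs in 172 of those 174 pairs, with a median shCTRL-to-shPml UMI ratio of 0.339 (quartiles 0.315 and 0.393). All 14 cells of the unnamed subcluster 5 and all 6 epithelial-like cells of the shCTRL library were shared in the same way. In the other direction, 13 of 17 shCTRL monocyte or macrophage-like barcodes and 26 of 80 regulatory T-like barcodes were shared, with a median of 13.5 and 14.2 times as many UMIs in the shCTRL library. Naive T-like cells of the shCTRL library shared 9 of 435 barcodes (2.07%), and those of the shPml library 14 of 53 (26.4%). Of the barcodes over the mitochondrial limit, 5 of 1388 in the shCTRL library (0.3602%) and 3 of 514 in the shPml library (0.584%) were shared. Among shPml CD8 T-like cells, the shared portion was 3 of 561 cells with 500 to 1000 UMIs (0.535%), 75 of 126 cells with 2000 to 3000 UMIs (59.5%) and 44 of 47 cells with 3000 to 5000 UMIs (93.6%). At the median ratio of 0.339, a shPml cell with few UMIs would have a shCTRL copy under the minimum of 500 UMIs. Sharing of such cells could therefore not be seen. Shared barcodes were singled out after their values were seen.

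**Figure D2:**
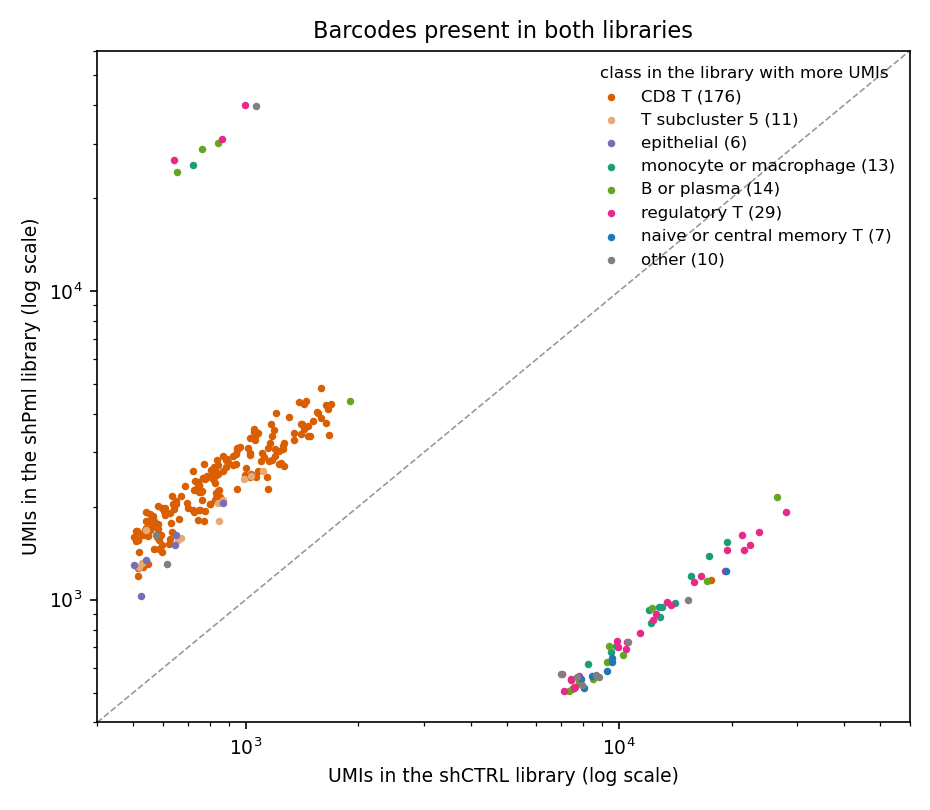
UMIs of each of the 266 barcodes found in both libraries, in the shCTRL library (x axis, log scale) and the shPml library (y axis, log scale), coloured by the class in the library with more UMIs. The dashed line marks equal counts, and 172 of 174 shCTRL CD8 T-like barcodes lie above it, with a median shCTRL-to-shPml ratio of 0.339.

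The CD8 T-like cells also differed from the other leukocytes in transcripts of the sex chromosomes. Xist, the RNA that silences an X chromosome in female cells, stood at 37.3 CPM (28.5 to 48.0) in shPml CD8 T-like cells. It stood at 1297 CPM (1172 to 1432) in regulatory T-like, 772 in naive T-like and 1161 in B or plasma-like cells of the same library. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together gave 278 UMIs in 233 of the 1235 shPml CD8 T-like cells (173 CPM). They gave 0 UMIs in shPml regulatory T-like and neutrophil-like cells, with upper bounds of 12.2 and 5.14 CPM. In shCTRL CD8 T-like cells Y-linked genes stood at 114 CPM and Xist at 135 CPM, whereas shCTRL naive T-like cells had 0 Y-linked UMIs and 651 CPM of Xist. T cell receptor beta variable segments followed the same line: Trbv13-1 gave 24 of 25 such UMIs in shPml CD8 T-like cells and 8 of 8 in shCTRL CD8 T-like cells, against 13 segments over 45 UMIs in shCTRL naive T-like cells. T subclusters 0 to 5 and the epithelial-like cluster had more cells with Y-linked than with Xist UMIs, and together held 1302 shPml cells (74.4%) and 198 shCTRL cells (23.2%). Outside them, 11.8% of 449 shPml cells and 66.5% of 654 shCTRL cells were naive T-like, a ratio of 0.177 (0.131 to 0.236). Regulatory T-like cells there held 12.2% in both libraries, a ratio of 1.001 (0.697 to 1.43). Over the T and NK-like cells left there (117 and 531), naive T-like cells held 45.3% and 81.9%, a ratio of 0.553 (0.408 to 0.737), and regulatory T-like cells 47.0% and 15.1%, a ratio of 3.12 (2.17 to 4.45). The Xist, Y-linked and receptor segment genes were chosen after their values were seen, and the labels do not give the sex of the mice.

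**Figure D3:**
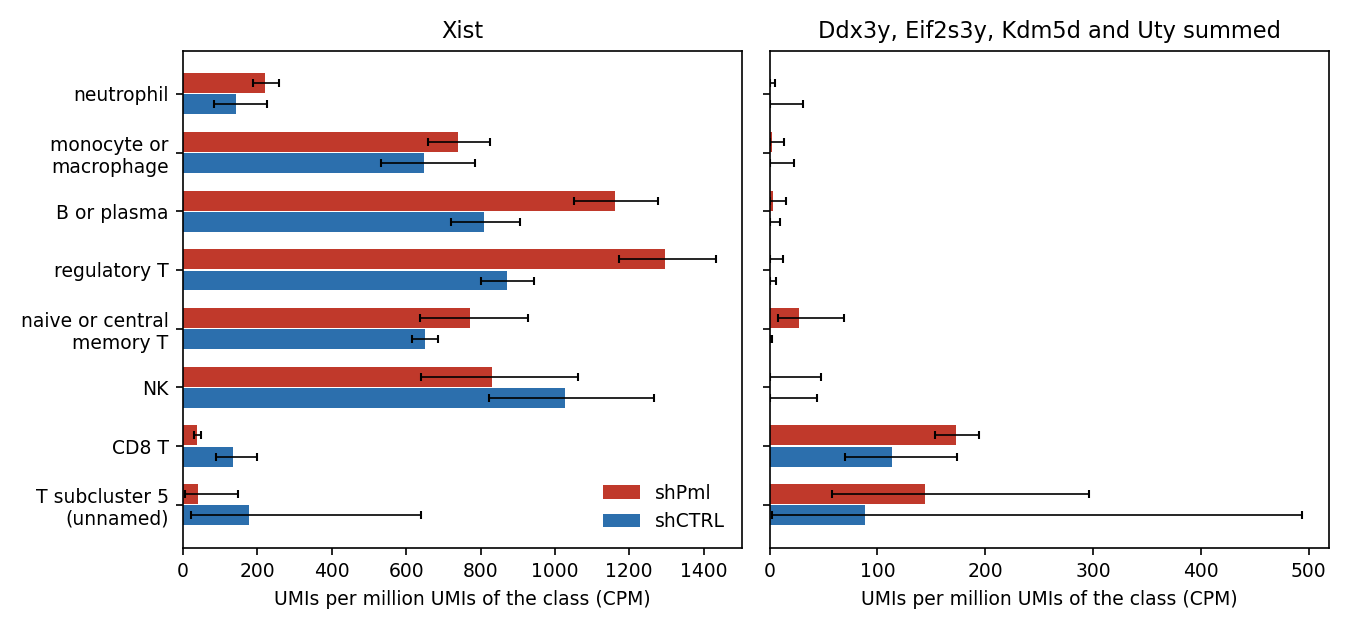
Level of Xist (left) and of the summed Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty (right), in CPM (x axis), for each class (y axis) in the shPml (red) and shCTRL (blue) libraries. Error bars are exact 95% Poisson intervals; Y-linked UMIs stood at 173 CPM in shPml CD8 T-like cells, and Xist at 1297 CPM in shPml regulatory T-like cells.

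Neutrophil-like cells of the shPml library had higher levels of interferon-stimulated and granule genes than those of the shCTRL library. In the type I interferon response list, 21 of 24 measured members were above 0, with a median log2 ratio of 0.61 (counting interval 0.37 to 1.05), at percentile 99.99 of 10000 random lists matched on expression. Such percentiles describe these libraries only. Rsad2, which encodes the antiviral enzyme viperin, stood at 1590 CPM against 514 (log2 1.63, 1.26 to 2.02), the ubiquitin-like modifier gene Isg15 at 2280 against 1053 (log2 1.11, 0.85 to 1.39) and Slfn5 at 182 against 49.7 (log2 1.87, 0.71 to 3.35). The immature granule list had a median of 0.60 (0.19 to 0.75, percentile 99.99, 7 of 11 above 0). Its cathelicidin gene Camp stood at 780 against 33.2 CPM (log2 4.56, 3.19 to 6.44), Ngp at 2210 against 174 (log2 3.67, 3.05 to 4.36) and the lactoferrin gene Ltf at 781 against 41.5 (log2 4.24, 3.005 to 5.86). The mature neutrophil list lay at -0.14 (percentile 7.56), with Retnlg lower in the shPml library (log2 -1.41, -1.51 to -1.31) and S100a8 higher (log2 0.36, 0.32 to 0.40). The tumour-infiltrating neutrophil list lay at 0.06 (percentile 57.4), although its members Spp1, encoding osteopontin, and the angiogenic factor gene Vegfa were lower in the shPml library (log2 -1.70, -1.90 to -1.51, and -1.61, -2.15 to -1.05). Inflammatory cytokines and NF-kB targets lay at -0.10 (percentile 20.03), with Il1a at log2 -1.21 (-1.46 to -0.95) and Tnf at -1.12 (-1.52 to -0.71). Dissociation and immediate early genes, a sign of handling, lay at 0.38 (percentile 99.8), with Hspa1b at log2 -1.45 (-1.85 to -1.04) and Ier3 at 0.76 (0.56 to 0.97). Among chemokines, Cxcl10, an interferon-induced attractant of T cells, stood at 503 against 149 CPM (log2 1.75, 1.07 to 2.52). The neutrophil attractants went both ways, with Cxcl1 at log2 -1.55 (-1.86 to -1.23) and Cxcl2 at 0.48 (0.43 to 0.53). In the granule list 1 shPml cell held 30.4% of the UMIs, and without the top cell of each library the median was 0.41. Without shared barcodes, which leaves 31 shCTRL neutrophil-like cells, the interferon median was 0.29 and the granule median 1.44.

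Monocyte or macrophage-like cells of the shPml library had higher levels of chemokine and glycolytic genes, and lower levels of dissociation and immediate early genes, over 54 and 17 cells. Monocyte-attracting chemokines had a median log2 ratio of 1.62 (1.16 to 1.95, percentile 99.99, 6 of 8 above 0). Ccl12 stood at 415 against 18.2 CPM (log2 4.51, 2.94 to 6.80), Ccl9 at 1180 against 267 (log2 2.14, 1.70 to 2.62) and Ccl6 at 2160 against 606 (log2 1.83, 1.53 to 2.15). All 19 measured hypoxia and glycolysis genes were above 0 (median 0.97, 0.77 to 1.05, percentile 100), among them Vegfa (log2 2.74, 1.91 to 3.72), Mif (1.27, 0.83 to 1.75) and the glycolytic enzyme gene Gapdh (0.9997, 0.82 to 1.18). MHC class II genes had a median of 0.51 (0.44 to 0.64, percentile 97.1), within the middle 95% of random lists, and MHC class I genes lay at 0.11 (percentile 61.8, 9 of 15 above 0). Within class II, H2-Ab1 stood at log2 1.16 (0.98 to 1.34), H2-DMb1 at 1.19 (0.62 to 1.81) and H2-Eb1 at 0.63 (0.47 to 0.80). Type I interferon genes had a median of 0.63 (0.35 to 1.05, percentile 99.9, 19 of 24 above 0), with Isg15 at 1.33 (0.75 to 1.96) but Bst2 at -1.69 (-2.001 to -1.39). Ifit1 had 22 and 0 UMIs, log2 1.504 against a floor of 3 counts (exact lower limit 1.08). Dissociation and immediate early genes had a median of -0.99 (-1.15 to -0.76, percentile 0, 2 of 16 above 0), with Hspa1b at -1.96 (-2.12 to -1.80), Jun at -1.74 (-1.93 to -1.54) and Hspa1a at -1.67 (-1.83 to -1.52). Inflammatory cytokines and NF-kB targets lay at 0.64 (percentile 99.6). Its member Nos2, encoding inducible nitric oxide synthase, had 43 and 0 UMIs, log2 2.47 against the floor (exact lower limit 2.11). Il1b stood at 1.14 (1.02 to 1.27). Myeloid suppressor genes lay at 0.82 (percentile 99.96), led by the neutrophil genes S100a8 (log2 6.43, 5.07 to 8.31) and S100a9 (6.55, 4.69 to 9.60). Lists of neutrophils were higher beside these: mature neutrophil genes lay at 0.98 (0.71 to 1.20, percentile 99.9, 9 of 11 above 0), tumour-infiltrating neutrophil genes at 0.69 (0.34 to 0.90, percentile 99.4) and immature granule genes at 0.64 (-0.26 to 1.05, percentile 96.5). Among their members Lcn2 had 33 and 0 UMIs (log2 2.09 against the floor, exact lower limit 1.71). Whether neutrophil RNA or doublets gave the counts of these neutrophil genes was not tested. The alternatively activated (0.37), lipid-associated (0.30), complement and resident (0.10) and TGF-beta response (0.34) lists lay between percentiles 58.1 and 89.6. Within them Chil3 stood at log2 4.90 (3.33 to 7.18), Cd209a at -2.37 (-3.30 to -1.49), Spp1 at 2.17 (1.35 to 3.11), Fabp5 at -1.95 (-2.47 to -1.44), Pltp at -2.04 (-2.79 to -1.31), Selenop at -1.28 (-1.81 to -0.75) and Itgae at -3.09 (-4.55 to -1.82). The PML nuclear body list lay at -0.65 (-0.89 to -0.17, percentile 1.19, 1 of 9 above 0), with the SUMO gene Sumo2 at -0.65 (-1.15 to -0.13) and the chromatin remodeller gene Atrx at -1.02 (-1.97 to -0.04). The class also held dendritic cell transcripts, such as Siglech (120 CPM over both libraries) and Klk1 (254 CPM) of plasmacytoid cells and Xcr1 (67.6 CPM) of conventional cells. With every barcode clustered, plasmacytoid dendritic-like barcodes numbered 5 and 4. Whether a difference in dendritic cells set the ratios of their markers Bst2 and Cd209a was not tested. Without shared barcodes only 4 shCTRL cells remained, and the interferon and glycolysis medians turned to -0.99 and -0.55. The NF-kB target and lipid-associated medians turned to -0.80 and -0.46 there, and the chemokine median was 0.69. Without the cells in the top 5% of UMIs, which leaves 19 and 7 cells, single genes turned too, such as Ccl9 to -2.14 and Hspa1b to 2.13.

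B or plasma-like cells of the shPml library had lower levels of antigen presentation genes and higher levels of cell cycle genes, over 64 and 72 cells. Of 11 MHC class II genes, 1 was above 0 (median -0.42, -0.48 to -0.25, percentile 0.125). The invariant chain gene Cd74 stood at 14406 against 20497 CPM (log2 -0.51, -0.56 to -0.46), H2-Aa at 5470 against 7341 (log2 -0.42, -0.51 to -0.34) and H2-DMb2 at 638 against 951 (log2 -0.58, -0.82 to -0.33). MHC class I genes had a median of -0.34 (percentile 0.465), with H2-D1 at -0.68 (-0.80 to -0.56) and H2-Q7 at -0.66 (-1.04 to -0.29). All 14 measured proliferation genes were above 0 (median 1.04, 0.82 to 1.46, percentile 100), among them the mitotic ubiquitin-conjugating enzyme gene Ube2c (log2 3.16, 1.68 to 5.11), Pclaf (1.65, 0.97 to 2.38) and Cdk1 (2.69, 0.93 to 5.09). Oxidative phosphorylation genes lay at 0.25 (percentile 98.3), and turned to -0.30 with at least 500 genes and at most 5% mitochondrial UMIs. Members included Atp5b at 0.78 (0.43 to 1.13) and Cox4i1 at 0.68 (0.41 to 0.95). Dissociation and immediate early genes lay at -0.44 (percentile 0.010), with Fos at -1.17 (-1.49 to -0.87) and Jund at -0.97 (-1.09 to -0.84). In the proliferation list 1 shPml cell held 47.8% of the UMIs and 1 shCTRL cell 39.7%. After thinning to 500 UMIs, cycling cells numbered 1 of 64 and 3 of 72, and without thinning they made up 42.2% and 38.9%. Without shared barcodes the proliferation median was 0.39, and with at least 500 genes and at most 5% mitochondrial UMIs the MHC class II median was -0.02 over 9 and 31 cells.

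In CD8 T-like subclusters 0 to 4, the values below set 1235 shPml cells against 178 shCTRL cells, of which 174 (97.8%) carried barcodes of the shPml library. They describe the counts of these barcodes and cannot be read as a difference between the groups, and they were not computed without the shared barcodes because 4 shCTRL cells would remain. Pdcd1, which encodes the inhibitory receptor PD-1, stood at 204 against 465 CPM (log2 -1.19, -1.53 to -0.83), and Havcr2, encoding TIM-3, at 21.1 against 75.7 (log2 -1.84, -2.78 to -0.83). Together with Tnfrsf9 (log2 -0.54, -0.87 to -0.20) they belong to the exhaustion and checkpoint list, of whose 11 measured members 1 was above 0 (median -0.35, -0.65 to -0.11, percentile 0.295). The cytotoxic effector list lay at -0.21 (-0.34 to 0.07, percentile 1.09), with the granzyme genes Gzma (log2 -0.76, -1.19 to -0.31) and Gzmb (-0.41, -0.61 to -0.20) lower and Ccl5 higher (0.87, 0.74 to 0.997). The rule for named genes also took, as higher in the shPml library, Tmem97 with 68 and 0 UMIs (log2 1.38 against the floor, exact lower limit 1.04). With it came the nuclear export factor gene Xpo1 (2.24, 0.66 to 4.53), Ankrd12 (2.11, 0.72 to 4.00) and the monocyte and memory T cell marker Ly6c2 (1.25, 0.62 to 1.96). Also higher were S1pr1, the receptor that guides lymphocytes out of tissue (1.51, 0.43 to 2.84), Zfp36l2 (0.75, 0.35 to 1.18), Emp3, Kxd1, Arhgap31, Fam168b and Hikeshi. As lower in the shPml library it took, beside Pdcd1, Nrn1 (log2 -1.34, -1.97 to -0.66), Serpinb6a (-1.40, -2.13 to -0.63), the class I gene H2-D1 (-0.64, -0.78 to -0.51), the chemokine receptor gene Cxcr6 (-0.84, -1.17 to -0.49), Uhrf2 (-0.87, -1.28 to -0.44), Ubac1, Lbh, Cpsf2, Smim3, Adipor2 and Arhgef1. Ccl5 and Ly6c2 lead subcluster 3, which held 221 and 10 cells, and Nrn1 and Cxcr6 lead subclusters 1 and 2. Naive and memory T cell genes lay at -0.19 (percentile 8.27), with Il7r at -1.56 (-2.36 to -0.70), and proliferation genes at 0.06 (percentile 80.2), with Mcm5 at -0.79 (-1.27 to -0.28) and Hmgb2 at 0.24 (0.05 to 0.43). Interferon gamma response genes lay at -0.07 (percentile 30.7). The PML nuclear body list lay at 0.21 (percentile 91.8), although its member Sp110 stood at -0.95 (-1.75 to -0.07). Genes of other cell types also differed within these cells. The regulatory T cell programme lay at -0.46 (-0.69 to -0.18, percentile 0.050, 0 of 8 above 0), with Tnfrsf18 at -0.83 (-1.38 to -0.23) and Ikzf2 at -0.69 (-1.25 to -0.09). MHC class II genes lay at -0.94 (-1.44 to -0.15, percentile 0.010, 1 of 7 above 0), with Cd74 at -1.71 (-2.18 to -1.21) and H2-Aa at -1.36 (-2.28 to -0.34). The neutrophil gene S100a8 went the other way, at 70.2 against 27.0 CPM, and whether such counts came from free RNA, doublets or carried reads was not tested. With at least 500 genes and at most 5% mitochondrial UMIs, which leaves 195 and 45 cells, the checkpoint median turned to 0.55, the cytotoxic median to 1.64 and the MHC class II median to 2.46.

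Regulatory T-like cells, 55 and 80 of them, had a median near 0 for their programme genes, and the direction of their proliferation genes depended on the cells kept. The regulatory T cell programme had a median log2 ratio of 0.09 (-0.00 to 0.34, percentile 87.2, 8 of 12 above 0). Within it the Ikaros family gene Ikzf4 stood at 92.4 against 41.2 CPM (log2 1.17, 0.35 to 1.99), the costimulatory receptor gene Icos at 0.39 (0.14 to 0.65) and Tnfrsf18, encoding GITR, at 0.40 (0.10 to 0.70). Of 20 proliferation genes 16 were above 0 (median 0.30, 0.16 to 0.48, percentile 99.4), among them the proliferation marker Mki67 (log2 1.15, 0.68 to 1.62), Pclaf (0.86, 0.44 to 1.28) and Stmn1 (0.64, 0.32 to 0.96). With at least 500 genes and at most 5% mitochondrial UMIs, over 30 and 47 cells, the proliferation median was -0.23. One shPml cell held 21.9% and 1 shCTRL cell 32.6% of the proliferation UMIs, and without them the median was 0.71. Cycling cells made up 12.7% of shPml and 8.75% of shCTRL regulatory T-like cells after thinning to 500 UMIs (7 cells each), and 38.2% and 58.8% without thinning. MHC class II genes lay at 3.18, with 89.5% of their shPml UMIs in 1 cell. Without shared barcodes, over 39 and 54 cells, the proliferation median was 1.20 and the programme median 0.51.

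Naive or central memory T-like cells of the shPml library had higher levels of interferon-stimulated genes and lower levels of naive T cell genes, over 53 and 435 cells. Of 20 type I interferon genes 16 were above 0 (median log2 0.86, 0.33 to 0.94, percentile 100). The antiviral gene Ifit3 stood at 114 against 17.9 CPM (log2 2.67, 1.75 to 3.54), Ifit1 at 94.0 against 18.4 (log2 2.36, 1.36 to 3.27) and the tethering factor gene Bst2 at 222 against 120 (log2 0.88, 0.31 to 1.41). Interferon gamma response genes had a median of 0.54 (0.32 to 0.85, percentile 99.99), with Cxcl10 at 3.06 (2.03 to 4.04) and the PD-L1 gene Cd274 at 1.87 (0.94 to 2.71). None of 10 naive and memory T cell genes was above 0 (median -0.30, -0.62 to -0.25, percentile 1.66). Lef1 stood at 322 against 564 CPM (log2 -0.81, -1.25 to -0.39), the quiescence factor gene Klf2 at 1887 against 2745 (log2 -0.54, -0.72 to -0.37) and Ccr7 at 410 against 664 (log2 -0.70, -1.09 to -0.33). Genes of the regulatory T cell programme lay at 1.26 (0.78 to 1.66, percentile 100), with Ikzf2 at 2.95 (2.25 to 3.64) and Capg at 2.13 (1.28 to 2.92). Dissociation and immediate early genes lay at -0.35 (percentile 0.100), with Fos at -1.54 (-1.97 to -1.14) and Hspa1b at -0.79 (-0.94 to -0.64). The type I interferon list lay near 0 in B or plasma-like cells (median -0.13) and regulatory T-like cells (-0.18), over 9 and 13 measured members. In CD8 T-like cells the median was -0.00 over 9 members, but 174 of the 178 shCTRL cells there carried barcodes of the shPml library. That value cannot be read as a difference between the groups. Of the 53 shPml cells, 14 had shared barcodes, all with fewer UMIs than in the shCTRL library, where 7 were naive T-like and the others regulatory T-like or NK-like. Without shared barcodes the median was 0.75 for the regulatory T cell programme, 1.005 for interferon genes and -0.33 for naive and memory genes.

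**Figure D4:**
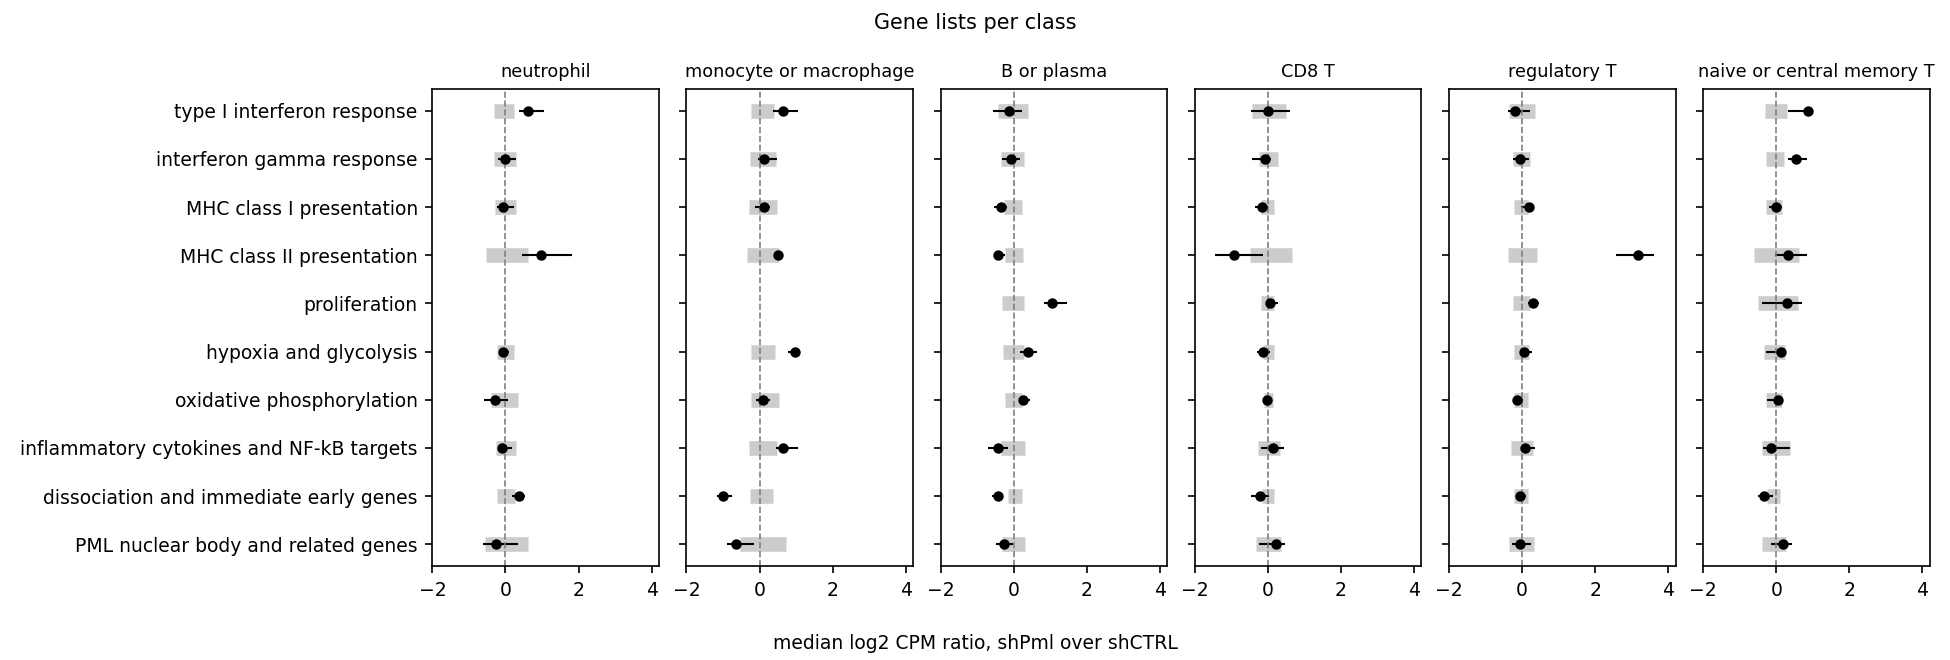
Median log2 CPM ratio, shPml over shCTRL (x axis), of 10 gene lists (y axis) in 6 classes (panels), as black points with bars for the counting interval. Grey bands hold the middle 95% of 10000 random lists matched on expression; the type I interferon point lies at 0.61 in neutrophil-like and 0.86 in naive T-like cells.

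Over all T cells together, cytotoxic, checkpoint and proliferation genes were higher and naive and immediate early genes lower in the shPml library, over 1388 and 707 cells. CD8 T-like subclusters held most of these cells in the shPml library and the naive subcluster in the shCTRL library, so the values carry that difference in makeup. Of the 1388 shPml cells 1235 were CD8 T-like, the class with Y-linked UMIs and little Xist. Of the 178 shCTRL CD8 T-like cells, 174 carried barcodes of the shPml library. The values below therefore cannot be read as a difference between the groups. The median log2 ratio was 1.94 for the cytotoxic effector list (1.73 to 2.05, 13 of 15 above 0) and 2.09 for the exhaustion and checkpoint list (1.74 to 2.19, 12 of 13 above 0). It was 1.63 for the proliferation list (1.52 to 1.82, 20 of 20 above 0) and -1.41 for the naive and memory T cell list (-1.50 to -1.29, 0 of 10 above 0). Dissociation and immediate early genes lay at -1.001 (-1.09 to -0.92, percentile 0, 4 of 16 above 0). Named as higher in the shPml library were Ccl5 (log2 3.59, 3.49 to 3.68), the killer receptor gene Klrk1 (3.07, 2.69 to 3.47), the serpin gene Serpinb6b (2.75, 2.46 to 3.06), the granzyme genes Gzma, Gzmb and Gzmk, and Xcl1, Nrgn, Hist1h1b, Grb7, Perp and Bend4. Named as lower were Clca3a1 (log2 -4.96, -6.85 to -3.58), the immediate early gene Fos (-2.87, -3.07 to -2.68), the heat shock gene Hspa1b (-2.55, -2.64 to -2.47), Tgfbr3, Sox4, Vipr1 and St8sia6. Igfbp4, Pik3ip1, Pdlim4, Tdrp and Auts2, also named as lower, lead the naive T cell clusters. The type I interferon list lay at -1.04 over all T cells (-1.19 to -0.81, percentile 0, 3 of 25 above 0), opposite to its direction in naive T-like cells. Pml itself stood at 20.9 against 38.0 CPM over all T cells (log2 -0.87, -1.40 to -0.35), while its ratio within each named T cell class had an interval holding 0.

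Shares of cells with at least 1 UMI of a gene were compared after thinning every cell to 500 UMIs, which left out 0 cells. The CD8 T-like shares below cannot be read as a difference between the groups, because 174 of 178 shCTRL cells carried barcodes of the shPml library. In CD8 T-like cells Pdcd1 was detected in 7.69% of shPml cells (6.27 to 9.32%) and 15.2% of shCTRL cells (10.2 to 21.3%), and Gzmb in 28.3% (25.8 to 30.9%) and 33.7% (26.8 to 41.2%). Before thinning the Pdcd1 shares were 18.5% and 24.2%, and the Gzmb shares 38.6% and 43.8%. In B or plasma-like cells, which should lack them, Pdcd1 was detected in 1 of 64 and 0 of 72 thinned cells and Gzmb in 0 of 64 and 0 of 72. Median depths were 1141 and 828.5 UMIs in CD8 T-like and 3864 and 4449 UMIs in B or plasma-like cells. Cells with at least 2 UMIs of proliferation markers made up 29.8% of shPml (27.3 to 32.4%) and 34.8% of shCTRL CD8 T-like cells (27.9 to 42.3%), and 0 of 214 and 0 of 34 neutrophil-like cells. Without thinning the cycling shares were 46.9% and 44.4%. Cd274, encoding PD-L1, was detected in 34.1% (27.8 to 40.9%) and 47.1% (29.8 to 64.9%) of thinned neutrophil-like cells, against 2.43% and 0.562% of CD8 T-like cells, and in 64.0% and 76.5% without thinning. Foxp3 was detected in 7 of 55 and 9 of 80 thinned regulatory T-like cells (32.7% and 33.8% without thinning), with 0 in thinned B or plasma-like cells.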

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

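All tests in this part were chosen after the result was seen. Signals also lay outside the planned comparisons of shares and levels: 266 barcodes were present in both libraries, most of them among the analysed cells. The Y-linked genes, which were left out of the rule for named genes, gave 278 UMIs in the CD8 T-like cells of the shPml library. In the shCTRL library 1388 barcodes lay over the mitochondrial limit and were left out.

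The CD8 T-like share was higher in the shPml library, with a ratio of 3.59 by clusters and 1.67 (1.45 to 1.93) by gates on marker genes. By clusters it was 80.5 (36.9 to 220) without the copy of a shared barcode with fewer UMIs, over 6 shCTRL cells. That setting takes out nearly all shCTRL CD8 T-like cells. It keeps shPml cells whose shCTRL copy would fall under the minimum of 500 UMIs, so this ratio cannot measure enrichment. The limit on mitochondrial UMIs was argued against as the cause, because with every barcode kept the ratio of shares was 7.25 (6.27 to 8.42). An origin of the CD8 T-like cells in the same animals as the other leukocytes was argued against too, because the CPM of Xist in the shPml CD8 T-like cells was 0.0332 times that in its regulatory and naive T-like cells (0.0249 to 0.0434). Copies of shCTRL cells in the shPml library were argued against as the cause of the higher share. Of the shPml CD8 T-like barcodes, 0.648% (0.280 to 1.27%) had more UMIs in the shCTRL library, a count that the minimum of 500 UMIs cannot lower. That count cannot decide whether reads of another source entered both libraries. The shCTRL CD8 T-like cells may be copies of shPml cells or reads of another source in both libraries. Some shared barcodes had a wider gap, such as 30092 UMIs in the shPml library against 844 (B or plasma-like). CD8 T-like pairs had a median of 2.93 times as many UMIs in the shPml library, and epithelial-like pairs 2.42. Carry-over from the shPml library at a fixed rate does not give both gaps. Where the CD8 T-like cells came from, and whether Pml knockdown alters CD8 T cell entry, stays untested with 1 library per group.

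The naive T-like share was higher in the shCTRL library. Copies of shPml cells were argued against, because 0.4598% (0.0557 to 1.65%) of the shCTRL naive T-like barcodes had more UMIs in the shPml library. The mitochondrial limit was argued against as the whole cause, with a ratio of 0.197 (0.174 to 0.224) with every barcode kept. That denominator still held the CD8 T-like cells, 1394 of 1782 shPml and 210 of 1946 shCTRL barcodes. The limit and the clusters with Y-linked transcripts were not taken out together, so their joint part was not tested. The clusters with Y-linked transcripts were argued against as the whole cause, although over the T and NK-like cells outside them the ratio was 0.553 (0.408 to 0.737), nearer to 1 than the 0.0631 with them. Lymph node tissue in the shCTRL sample cannot be told apart from a difference in the tumours, because the B or plasma-like ratio outside those clusters was 1.29 with an interval holding 1 (0.910 to 1.84). An effect of the knockdown also stays open, since each group had 1 library.

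Type I interferon genes were higher in neutrophil-like and naive T-like cells of the shPml library. Without the top cell of each library the lower of the 2 medians, in neutrophil-like cells, was 0.72 (0.38 to 1.09). There the top shCTRL cell held 16.9% of the list's UMIs and the top shPml cell 8.79%. Leaving out both tends to raise the ratio, so this cannot decide whether a few cells set it. In naive T-like cells the top shPml cell held 15.1% and the top shCTRL cell 6.22%. The median there was no lower than 0.72, which argued against the top shPml cell alone as the cause there. Free RNA of the shPml library was argued against, because the higher of the medians in B or plasma-like and regulatory T-like cells was -0.13 (-0.55 to 0.23, in B or plasma-like cells). Without shared barcodes the median in naive T-like cells was 1.005 (0.37 to 1.11), which argued against copies there. In neutrophil-like cells, with 31 shCTRL cells left, it was 0.29 (0.05 to 0.68), a value that cannot decide by itself. Of 214 shPml neutrophil-like barcodes 3 were shared, all with fewer UMIs than in the shCTRL library. Of 34 shCTRL neutrophil-like barcodes, 0 had more UMIs in the shPml library. These counts argue against copies between the libraries as the cause there, although the median depended on the shared cells left out. A response to the Pml knockdown and a difference between single mice or preparations stay untested.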

How the results depend on the processing

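The settings that leave out shared barcodes, Y-linked clusters or the cell with most UMIs of a gene list, and those at 20% mitochondrial UMIs, at 2000 UMIs and with every barcode for T cell subclasses, were chosen after seeing the data; the others were chosen before the data were examined. Where no cause is named below, the cause was not tested.

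With every barcode kept, the ratio of shares was 5.80 for neutrophil-like, 4.01 for monocyte or macrophage-like, 0.731 for B or plasma-like, 7.25 for CD8 T-like, 0.908 for regulatory T-like, 0.197 for naive T-like and 0.917 for NK-like cells. With at least 2000 UMIs these were 8.24, 3.63, 0.998, 115 (3 shCTRL cells), 1.01, 0.148 and 0.984, and 0.614 for T and NK-like cells as a whole, whose ratio in the main setting was 0.940 (0.859 to 1.03). At 20% mitochondrial UMIs the regulatory T-like ratio was 0.554.

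Outside the clusters with more Y-linked than Xist cells the neutrophil-like ratio was 9.17, the monocyte or macrophage-like 4.63, the B or plasma-like 1.29 and the T and NK-like 0.321, since that setting takes out most shPml cells by construction. Over T and NK-like cells there, the regulatory T-like ratio turned to 3.12 and the NK-like to 2.55, and the naive T-like ratio was 0.553, since no CD8 T-like cells remain in the denominator. Without shared barcodes the ratios were 4.07 for monocyte or macrophage-like, 112 for CD8 T-like and 0.0389 for naive T-like cells, because 4 shCTRL cells remained in each of the first 2. Without the copy with fewer UMIs they were 80.5 for CD8 T-like (6 shCTRL cells), 0.207 for regulatory T-like and 0.0355 for naive T-like cells.

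With at least 500 genes and at most 5% mitochondrial UMIs the ratio was 0.221 for B or plasma-like and 0.688 for T and NK-like cells. Assigning each cell by itself gave 0.794 for T and NK-like cells, and gates on Cd8a or Cd8b1, Cd4 and Foxp3 gave 1.67 for CD8 T cells. At Leiden 2.0 within T and NK-like cells the regulatory T-like ratio was 1.59, because the subcluster with Foxp3 among its leading genes stayed unnamed and another took the name.

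With at least 500 genes and at most 5% mitochondrial UMIs the list medians were 0.39 for MHC class II and 0.61 for glycolysis in monocyte or macrophage-like cells, and -0.018 for MHC class II and -0.30 for oxidative phosphorylation in B or plasma-like cells. In CD8 T-like cells they were 1.64 for cytotoxic, 0.55 for checkpoint, 2.46 for MHC class II and -1.75 for mature neutrophil genes. In regulatory T-like cells they were -0.073 for cytotoxic, 0.37 for programme and -0.23 for proliferation genes, and -0.73 for naive genes in naive T-like cells.

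Without shared barcodes the medians in neutrophil-like cells were 0.29 for interferon and 1.44 for granule genes. In monocyte or macrophage-like cells, with 4 shCTRL cells left, they were -0.99 for interferon, 1.59 for MHC class II, 0.69 for chemokine, -0.80 for NF-kB target, -0.46 for lipid-associated, -0.55 for glycolysis and -0.61 for immediate early genes. B or plasma-like proliferation was 0.39. Regulatory T-like cells gave -0.045 for cytotoxic, 0.51 for programme and 1.20 for proliferation genes, and naive T-like cells 1.005 for interferon genes. Without the cell with most UMIs of the list in each library the medians were 0.81 for MHC class II and 1.37 for glycolysis in monocyte or macrophage-like cells, and -0.51 for cytotoxic and 0.71 for proliferation genes in regulatory T-like cells.

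Without cells in the top 5% of UMIs, which leaves 19 and 7 monocyte or macrophage-like cells, single genes there turned: Atrx to 1.66, Ccl12 to -0.34, Ccl6 to -0.58, Ccl9 to -2.14, Cd209a to 0.47, Fabp5 to 1.25, Gapdh to -0.080, Hspa1a to 1.97, Hspa1b to 2.13, Il1b to -0.91, Itgae to 0.078, Jun to 0.40, Mif to -0.87 and Spp1 to -2.21. With members of at least 5 summed UMIs the mature neutrophil median in regulatory T-like cells turned to 0.60. Without the top 5%, Slpi in B or plasma-like cells turned to -0.49 and H2-Aa in regulatory T-like cells to -1.36.

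For values that answer a comparison, 87 planned and 45 added checks stayed within the counting interval with the same direction, 13 and 34 moved, and 3 and 6 turned. For single genes and further lists 688 planned and 75 added checks stayed, 65 and 25 moved, and 21 and 4 turned. Shares of epithelial-like cells without shared barcodes have no value because 0 shCTRL cells remain. Gene lists in CD8 T-like cells were not computed without shared barcodes or without the copy with fewer UMIs, settings that leave 4 and 6 shCTRL cells. Fewer than 5 members remained for B or plasma-like proliferation and interferon genes, and for regulatory T-like MHC class II genes, with at least 500 genes and at most 5% mitochondrial UMIs. The regulatory T-like MHC class II list also had no value without shared barcodes or without the cell with most of its UMIs, and mature neutrophil genes in B or plasma-like cells had none under the stricter filter or without shared barcodes. The regulatory programme in naive T-like cells and mature neutrophil genes in regulatory T-like cells had none under the stricter filter. With at least 50 summed UMIs there was none for mature neutrophil genes in B or plasma-like, regulatory T-like and CD8 T-like cells, granule genes in monocyte or macrophage-like cells, interferon genes in B or plasma-like cells, MHC class II genes in CD8 T-like cells, and TGF-beta response in monocyte or macrophage-like cells.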

Other observations

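Tests that leave out shared barcodes or the cell with most UMIs of a list were chosen after the results were seen. In neutrophil-like cells, MHC class II genes were higher in the shPml library (median log2 0.97, 0.45 to 1.82, percentile 99.8, 5 of 5 above 0), with H2-Aa at 142 against 41.5 CPM (log2 1.78, 0.51 to 3.43) and Cd74 at 256 against 149 CPM (log2 0.78, 0.08 to 1.57). One shPml cell held 23.1% of the UMIs of that list. In regulatory T-like cells the MHC class II median was 3.18 (2.56 to 3.61), with Cd74 at 1027 against 32.0 CPM, and 1 shPml cell held 89.5% of the list's UMIs.

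Transcripts of other cell types were also found in T and B cells. In regulatory T-like cells Gzma had 72 and 0 UMIs (log2 5.70 against the floor, exact lower limit 5.36) and Ccl5 stood at log2 2.67 (2.09 to 3.29). Their cytotoxic effector list had a median of 0.82 there (0.29 to 1.05), and 1 shPml cell held 47.4% of the UMIs. That median turned to -0.51 without the cell with most UMIs in each library, -0.045 without shared barcodes and -0.073 with at least 500 genes and at most 5% mitochondrial UMIs. The mature neutrophil list had a median of 2.14 in B or plasma-like cells (0.90 to 2.26), where 1 shPml cell held 88.7% of the UMIs, with Slpi at log2 2.14 (1.96 to 2.31) and S100a8 at 2.17 (0.73 to 3.93). In CD8 T-like cells it had a median of 1.38 (0.05 to 1.49), with S100a8 at 1.38 (0.11 to 3.03) and S100a9 at 1.08 (0.12 to 2.23), and it turned to -1.75 with at least 500 genes and at most 5% mitochondrial UMIs. In regulatory T-like cells the same list lay the other way, at -1.34 (-2.06 to -0.60, percentile 0.010, 2 of 5 above 0), with Ifitm1 at log2 -3.96 (-6.26 to -2.37) and S100a9 at 4.23 (2.52 to 6.60), and turned to 0.60 with members of at least 5 summed UMIs.

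With every barcode clustered, the classes differed in mitochondrial UMIs. The median was 42.2% in 293 shPml naive T-like barcodes and 29.0% in 1622 shCTRL naive T-like barcodes, of which 85.3% and 73.4% lay over the 10% limit. CD8 T-like barcodes had medians of 6.14% and 5.44%, with 7.32% and 3.81% over the limit, and neutrophil-like barcodes 0.545% and 0.622%.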
